A study of Mus musculus with 8 samples.

How the data were processed

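The samples were total RNA of mouse gastrocnemius muscle, isolated with an RNeasy kit and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. Group (m31 guide or control guide) and replicate number were taken from the sample titles, 4 libraries per group. The deposited table holds size-factor-normalised read signal, that is, read counts per gene divided by 1 factor per library; the submitters' processing notes name STAR and DESeq2, without versions. Those notes also name the human build GRCh38.p12, while the deposited gene identifiers are mouse Ensembl identifiers; the counting program, its strand setting, the annotation and any filter are not given in the sources used here. Without a known strand setting, reads of overlapping genes and near-identical copies cannot be assigned with certainty. The table has 11 value columns, of which 8 match the library names in the labels; the other 3 columns were not used.

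The table has 23013 entries: 23008 mouse genes and 5 entries named CK8, GNDM, TracrRNA, U6 and mini_VR, which belong to the construct and were kept out of the gene tests and library totals. These took 0.0230 to 0.142% of the reads. Symbols were looked up by identifier for 22979 genes; 29 had none and 16 shared a symbol with another gene and kept their identifier. Within each library, values were whole multiples of what 1 read is worth: 100% of values came out whole within 0.01 of a read, so read counts and depth (25157486 to 39210248 reads in genes per library) could be recovered. Count precision is high for most genes, so the spread between libraries limits the comparison; the median SE of a log2 difference was 0.15. For low genes the counts limit it, and a count of 0 allows up to 3 reads. Intervals are exact at the 95% level and cover counting error only.

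The design fixed before the data were examined foresaw a count test for raw counts and, for normalised values, a test on the log scale; the latter applied. Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend, intercept and group, all 8 libraries), for the 15960 genes with a mean value of at least 10. Differences are m31 minus control. P-values were adjusted by the Benjamini-Hochberg method over all genes tested and, for fixed gene lists, also over the list alone, with a threshold of 0.05. A fold change of low genes on this scale depends on the pseudocount. Single values were compared by exact two-sided permutation tests over the 70 arrangements. As an alternative chosen after seeing the data, edgeR 4.0.16 (quasi-likelihood test) was run on the recovered reads and called 1 of 16193 genes; DESeq2 1.42.0 on the recovered reads, planned beforehand, called 31 genes and gave no adjusted p for 4048.

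In all, 34 gene lists were fixed before the data were examined, covering laminins and their receptors, genes near Lama1, matrix, immune responses, fibre types, metabolism, stress and the other cell types of a muscle sample. The 33 with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, whose main test asks whether the genes of a list move one way on balance. Of the list members, 435 were measured and 36 were not. A list score is the mean log2 value of its members in a library, centred on the 8 libraries. In 5 lists, none of them past the threshold, the median, the mean and the direction of the test differed in sign. Genes were named by a rule fixed at the same time: every laminin chain, genes past the threshold with non-overlapping groups (up to 12 per direction), the measured genes near Lama1 and up to 4 members per list with the smallest unadjusted p; only a part of those is printed, and some are not reported here. Any other gene is said to have been picked out after its values were seen.

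The tests were tested on simulated data before use. Counts were drawn independently for each of about as many genes as measured, with a seeded set of 193 to 196 tested genes changed by known folds. Of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold, 24.0%, 68.4%, 98.0% and 99.5% were recovered in runs of 15793, 15802, 15803 and 15801 genes. False calls were 7, 6, 6 and 12 beside 47, 132, 192 and 194 recovered genes, so at 1.5-fold and 8-fold their share was above 0.05. Alternatives were each library left out, the replicate number as a block, no minimum or a mean of at least 50, quantile normalisation, recentring on library medians, pseudocounts of 0.5 and 5, library weights, a log2 difference of at least 1, an estimated correlation, Lama1 left out of the lists, sex-linked, immunoglobulin and haemoglobin genes left out, and DESeq2. Added after seeing the data were edgeR, leaving out m31 replicate 4 with control replicate 3, and the GNDM level as a covariate. No pair of libraries in a group was alike within sampling noise: the chi-square per degree of freedom between replicates was 14.3 to 57.9. Coordinates are from GENCODE M21 on GRCm38, not from the build in the submitters' notes. Tables were handled with Python 3.11.15 and pandas 2.3.3.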

Results

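RNA was sequenced from gastrocnemius, the large calf muscle of the hind leg, in 8 samples of wild-type C57BL/6J mice. All had received a gene-activating epigenome editing construct, named GNDM in the labels, packaged in AAV9, an adeno-associated virus serotype that reaches striated muscle after injection into the blood. In 4 samples the construct carried guide m31, which targets Lama1, and in 4 it carried a control guide without a target. Muscle was taken 11 weeks after injection into the tail vein; the labels give the age at injection as 7 weeks in one place and 7 to 12 weeks in another. Reads in mouse genes came to 34142447 to 37792459 per library with m31 and 25157486 to 39210248 with the control guide. Mitochondrial genes took 11.9 to 15.03% of these reads and the 10 most abundant genes 22.4 to 25.4%. The labels name each library but do not state that each came from a separate animal, so p-values measure the spread between these samples, which may in part be technical.

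The question the design poses is whether the m31 guide raises Lama1 in muscle and what else differs from muscle that received the same construct with a control guide. Lama1 encodes the laminin alpha-1 chain, which belongs to embryonic basement membranes and is scarce in adult muscle; the series title presents its activation as an approach to the congenital muscular dystrophy of Lama2 deficiency. Lama1 was higher in all 4 m31 libraries than in any control library, with 216 ± 93.6 normalised reads against 1.61 ± 2.02 (mean ± SD, n = 4 each). The difference was 6.60 ± 0.58 (SE) on the log2(value + 1) scale, with limma's adjusted p = 0.00372 over 15960 genes. The exact two-sided permutation test gave p = 0.0286, the smallest value that the 70 arrangements of the 8 libraries allow.

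Per library, Lama1 stood at 209, 295, 273 and 86.5 normalised reads in m31 replicates 1 to 4. Control replicates 1 and 3 stood at 4.18 and 2.25, from 5 and 2 reads. Control replicates 2 and 4 held 0 reads, which allows levels of up to 2.86 and 4.0 (3 reads). Pooled over libraries, 956 reads with m31 against 7 with the control guide, each divided by the summed size factors of its libraries, gave a ratio of 118, with an exact 95% counting interval from 56.8 to 293 that covers counting error only. At such low control values the log2 difference depends on the pseudocount, from 4.98 with 5 to 7.19 with 0.5. In the GENCODE annotation of the mouse build GRCm38, Lama1 (ENSMUSG00000032796) is a protein-coding gene on the plus strand of chromosome 17, from 67697259 to 67822647, and no other annotated gene overlaps it.

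**Figure D1:**
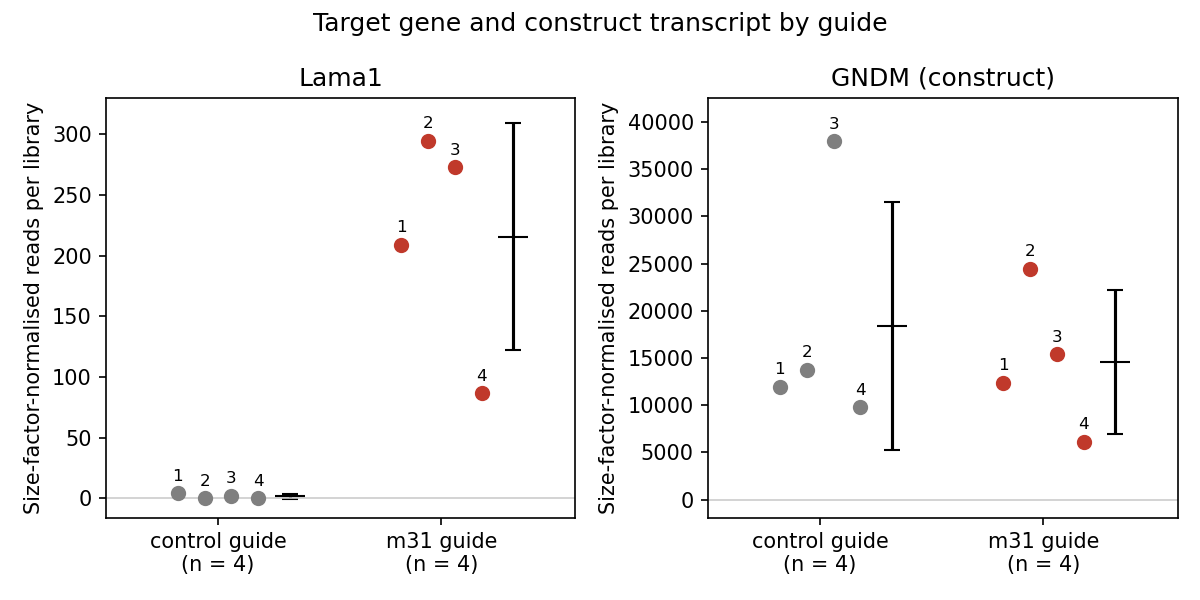
Size-factor-normalised reads of Lama1 (left) and of the construct entry GNDM (right) in each library. Points are numbered by replicate, and bars give the mean and SD of 4 libraries per guide. Lama1 lay between 86.5 and 295 with m31 and at 4.18 or below with the control guide, while GNDM overlapped between the groups.

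No other laminin chain passed the test among the 11 measured. Lama2, the alpha chain of adult muscle basement membrane, had 1522 ± 232 normalised reads with m31 and 1312 ± 409 with the control guide, a log2 difference of 0.25 ± 0.18 (SE). Mean Lama1 with m31 equalled 14.2% of mean Lama2 and 4.46% of the 5 alpha chain genes together. These are shares of normalised reads, not corrected for transcript length. They varied by library: in m31 replicates 1 to 4 Lama1 stood at 209, 295, 273 and 86.5 beside 1345, 1465, 1416 and 1861 of Lama2. The partner chains of the muscle laminins had log2 differences of 0.33 ± 0.20 (Lamb1), 0.12 ± 0.11 (Lamb2) and 0.28 ± 0.13 (Lamc1), and the vessel chains Lama4 and Lama5 of 0.25 ± 0.18 and -0.11 ± 0.19 (SE). The smallest adjusted p among these 10 other chains was 0.733, for Lamc1. Lama4 and Lamb1 were highest in control replicate 3 within their group, at 1543 and 1826 against at most 982 and 1119 in the other 3 control libraries. As a list, the laminin chains were higher with m31 (camera adjusted p = 0.00925; adjusted p = 0.577 with an estimated correlation), Lama1 being the 1 member past the threshold, both over all genes and adjusted over the list alone. Without control replicate 4 the list's adjusted p was 0.0849. The call rests on Lama1: with Lama1 left out, the other 10 chains had a mean log2 difference of 0.11 and did not pass (adjusted p = 0.171).

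**Figure D2:**
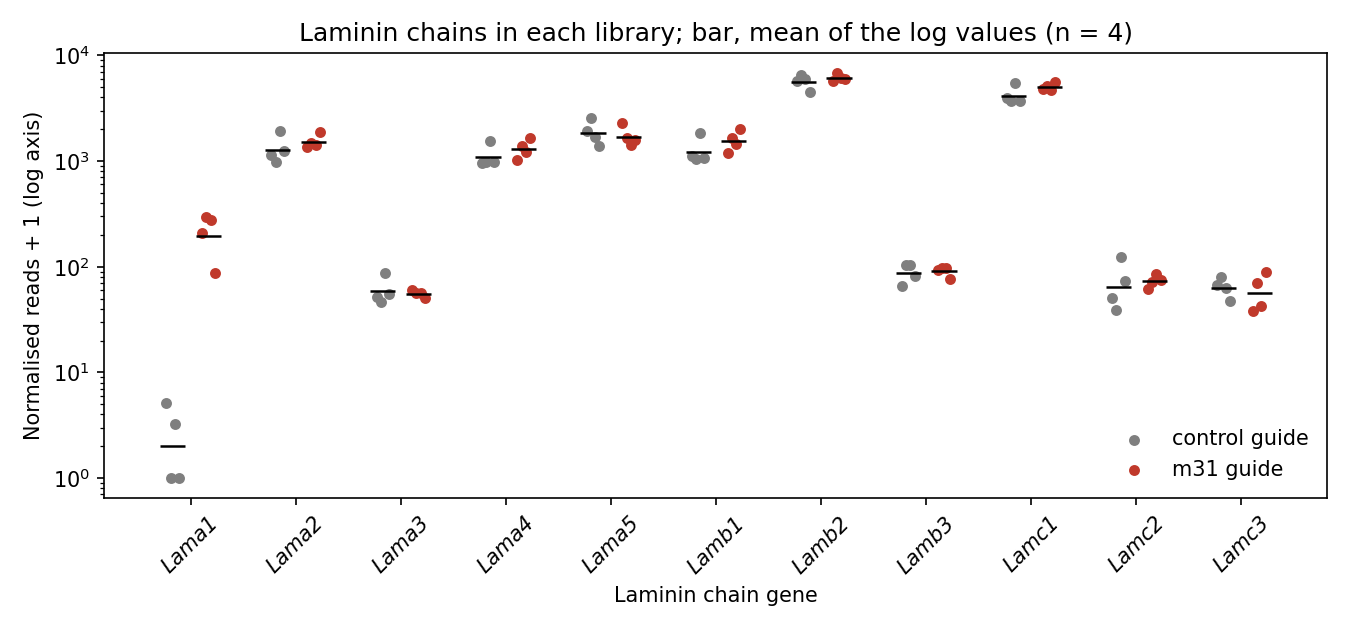
Normalised reads plus 1 (log axis) of the 11 laminin chain genes in each library, by guide, with a bar at the mean of the log values of 4 libraries. Lama1 is the chain whose m31 and control libraries lie far apart, at 86.5 or above against 4.18 or below.

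Reads assigned to the construct itself were present with both guides. Whether all of them came from transcripts was not tested. GNDM had 14607 ± 7631 normalised reads with m31 and 18384 ± 13170 with the control guide (mean ± SD, n = 4 each), and its level ranged 6.17-fold over the 8 libraries, from 6157 in m31 replicate 4 to 37989 in control replicate 3. For the 5 construct entries in the table (GNDM, mini_VR, CK8, U6 and TracrRNA), exact permutation tests between guides gave p = 0.457 to 0.771. The entry TracrRNA rested on 1 to 17 reads per library. In the 4 m31 libraries, Lama1 per 1000 GNDM reads was 16.9, 12.0, 17.7 and 14.1.

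The 7 measured genes of the fixed list of genes near Lama1 on chromosome 17 did not pass the test. That list was not drawn from the coordinates of all genes, so other genes of the interval may be missing from it. Arhgap28, which lies 20.1 kb beyond the end of Lama1, had 61.5 ± 15.7 normalised reads with m31 and 43.5 ± 6.31 with the control guide (log2 difference 0.46, adjusted p = 0.752). Lrrc30, 64.5 kb to the other side, had a log2 difference of 0.12, and Ptprm, a receptor tyrosine phosphatase gene 343 kb away, -0.08. Tmem200c, 1004 kb away, was above every control library in all 4 m31 libraries, at 15.2 ± 3.32 against 8.89 ± 2.11 (log2 difference 0.72, adjusted p = 0.720). The further genes Rab12, Epb41l3 and Zbtb14 had log2 differences of 0.01, 0.45 and 0.14. As a list these 7 did not pass (camera adjusted p = 0.0663; adjusted p = 0.577 with an estimated correlation), and none passed adjusted over the list alone.

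Laminin in muscle is held by integrins and by the dystrophin complex through sugar chains on dystroglycan. Of the 22 measured genes of these receptors and this complex, none passed over all genes and 1 passed adjusted over the list alone. That gene was Sntb1, the beta-1 syntrophin of the dystrophin complex, with 192 ± 33.7 normalised reads with m31 and 288 ± 39.4 with the control guide (log2 difference -0.59 ± 0.15, adjusted p = 0.627 over all genes). Dmd, the dystrophin gene, was lower in all 4 m31 libraries than in any control library, at 1990 ± 44.3 against 2281 ± 149, a log2 difference of -0.19. Neither these 22 genes nor the 14 measured genes of dystroglycan glycosylation, with B3galnt2 at 0.17 and Dpm1 at -0.35, passed as a list (camera adjusted p = 0.264 and 0.992).

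Across the genome, Lama1 was the 1 gene of 15960 past the threshold, and 0 genes were lower past it by limma; 1083 genes had an unadjusted p under 0.05 where chance gives 798, 600 of them higher and 483 lower. The groups did not overlap for 615 genes (3.85%; chance gives 2.86%). The next smallest adjusted p was 0.216, shared by Ephx3, Glcci1, Pthlh and Neto2, which were picked out after their values were seen. Neto2, an auxiliary subunit gene of kainate receptors, had 666 ± 175 normalised reads with m31 and 282 ± 54.7 with the control guide, and Pthlh, which encodes parathyroid hormone-related protein, 238 ± 39.1 and 105 ± 26.3. In simulated data with gene-wise spread taken from these libraries, 68.4% of 193 genes changed 2-fold and 24.0% of 196 changed 1.5-fold were recovered. There many genes changed at once and each gene was drawn independently, so that no library deviated as a whole. The adjustment is stricter where fewer genes change, so these shares may overstate what could be recovered in the real data. DESeq2 on the recovered whole reads placed 31 genes past the same threshold (22 higher, 9 lower), Neto2 and Pthlh among them, whereas edgeR's quasi-likelihood test on those reads placed 1, Lama1, with 1136 genes at an unadjusted p under 0.05.

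Genes of connective tissue were higher with m31 as lists while none of their members passed over all genes. Of 20 genes of interstitial matrix and fibrosis, 18 had positive estimates and the mean log2 difference was 0.64 (camera adjusted p = 1.7e-06; adjusted p = 0.577 with an estimated correlation). Col1a1, the main fibrillar collagen, had 23633 ± 21638 normalised reads with m31 and 7533 ± 2277 with the control guide (log2 difference 1.33, and 0.79 without m31 replicate 4), and Lox, which cross-links collagen, 729 ± 389 and 336 ± 157. All 10 tendon genes had positive estimates, with a mean of 0.72 (camera adjusted p = 2.7e-06; adjusted p = 0.577 with an estimated correlation), and 4 passed adjusted over the list alone: Thbs4 (log2 difference 1.01), Comp (0.99), Col12a1 (1.07) and Fmod (0.76). Among these, Col12a1 stood at 1927 normalised reads in m31 replicate 4 against 500 to 794 in the other m31 libraries. The fibro-adipogenic progenitor list, the stromal cells of muscle, had a mean of 0.23 (camera adjusted p = 0.00377; adjusted p = 0.683 with an estimated correlation), with Cd34 at 0.31 and Ly6a at 0.27. One library stood apart in these groups: m31 replicate 4 scored 1.34 on the matrix list, 1.15 on tendon and 0.54 on fibro-adipogenic progenitors (mean log2 value centred on the 8 libraries), against at most 0.05, 0.32 and 0.15 in the other 3 m31 libraries. Without m31 replicate 4 the matrix and tendon means were 0.30 and 0.46 (camera adjusted p = 0.000475 and 0.000346), and the progenitor list, with a mean of 0.08, was no longer past the threshold (adjusted p = 0.228; 0.104 without control replicate 2).

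Other basement membrane genes and genes of vessel wall cells were also higher as lists. Among 16 basement membrane genes other than laminins, 12 had positive estimates with a mean log2 difference of 0.23 (camera adjusted p = 0.00486; adjusted p = 0.683 with an estimated correlation). Fbln1, fibulin-1, had 705 ± 226 normalised reads with m31 and 391.8 ± 95.95 with the control guide, Col18a1 744 ± 211 and 502 ± 77.8, and the network collagen Col4a2 6208 ± 545 and 4717 ± 1243. None passed adjusted over the list alone, m31 replicate 4 scored highest at 0.48, and without it the list's mean fell to 0.11 (adjusted p = 0.172; 0.117 without control replicate 4). The pericyte and smooth muscle list had a mean of 0.24 over 10 genes, 7 with positive and 3 with negative estimates (camera adjusted p = 0.00324, and 0.577 with an estimated correlation). Its members Cnn1 (log2 difference 0.89), the pericyte receptor Pdgfrb (0.35) and Notch3 (0.34) passed adjusted over the list alone. Over all genes they did not pass (limma adjusted p = 0.647 each). In this list m31 replicate 2 rather than replicate 4 scored highest, at 0.32.

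Of 5 immune lists tested, 3 were higher with m31. All 16 macrophage genes had positive estimates, with a mean log2 difference of 0.64 (camera adjusted p = 2.7e-06; adjusted p = 0.577 with an estimated correlation). The Fc receptor gene Fcgr1 had 30.8 ± 13.5 normalised reads with m31 and 13.0 ± 8.70 with the control guide, and the mannose receptor gene Mrc1 551 ± 208 and 354 ± 184; no member passed, over all genes or adjusted over the list alone. The macrophage score was 1.17 in m31 replicate 4 and 0.54 in control replicate 3, against -0.71 to 0.24 in the other 6 libraries, and without m31 replicate 4 the mean was 0.36 (camera adjusted p = 0.00929). All 15 antigen presentation genes had positive estimates, with a mean of 0.31 (camera adjusted p = 0.000471; adjusted p = 0.577 with an estimated correlation), Psmb9 at 0.48 and Cd74 at 0.59. Cd74 stood at 4007 normalised reads in m31 replicate 4 against 1203 to 1699 in the other m31 libraries and 939 to 2018 in the control libraries. The type I interferon response had a mean of 0.20 over 26 genes (camera adjusted p = 0.0246; adjusted p = 0.820 with an estimated correlation), with Irf7 at 0.75 and Oasl2 at 0.49. Without m31 replicate 4, with scores of 0.76 and 0.41, the means fell to 0.11 and 0.10 and neither list passed (adjusted p = 0.158 and 0.481), and no member of either passed adjusted over the list alone. The interferon list was also lost without m31 replicate 1 (adjusted p = 0.427) or control replicate 1, 2 or 3 (0.167, 0.175 and 0.0652). The T and NK cell list (mean 0.23 over 4 measured genes, adjusted p = 0.734) and the B and plasma cell list (mean 0.01 over 4 genes, adjusted p = 0.992) did not pass, with Cd3e at 0.43 and Ighm at 0.13. Without m31 replicate 4 both means, over the members still measured, turned negative (-0.04 and -0.49, camera adjusted p = 0.868 and 0.282). With so few genes, not passing does not set these 2 lists apart from the lists that passed. Of 10 neutrophil genes 2 were measured, too few to test.

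Slow fibre and nerve genes were lower with m31 as lists. Of 12 slow fibre genes, 11 had negative estimates with a mean log2 difference of -0.34 (camera adjusted p = 3.4e-05; adjusted p = 0.577 with an estimated correlation). Tpm3, the slow tropomyosin, had 3817 ± 729 normalised reads with m31 and 5391 ± 274 with the control guide and passed adjusted over the list alone (log2 difference -0.52, adjusted p = 0.627 over all genes). Myh7, the slow myosin heavy chain, had 5192 ± 1534 and 7875 ± 1598, lower in all 4 m31 libraries than in any control library. The slow fibre score was -0.73 in m31 replicate 4, -0.15 to 0.25 in the other 3 m31 libraries and 0.03 to 0.28 in the control libraries, so the groups overlapped. Without m31 replicate 4 the list's mean was -0.15 (camera adjusted p = 0.00639). All 11 genes of Schwann cells and nerve had negative estimates, with a mean of -0.36 (camera adjusted p = 1.3e-05; adjusted p = 0.577 with an estimated correlation). Mbp, which encodes myelin basic protein, had a log2 difference of -0.38, and no member passed adjusted over the list alone. Control replicate 2 scored -0.26, within the range of the m31 libraries (-0.43 to -0.02), while the other 3 control libraries scored 0.23 to 0.42.

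**Figure D3:**
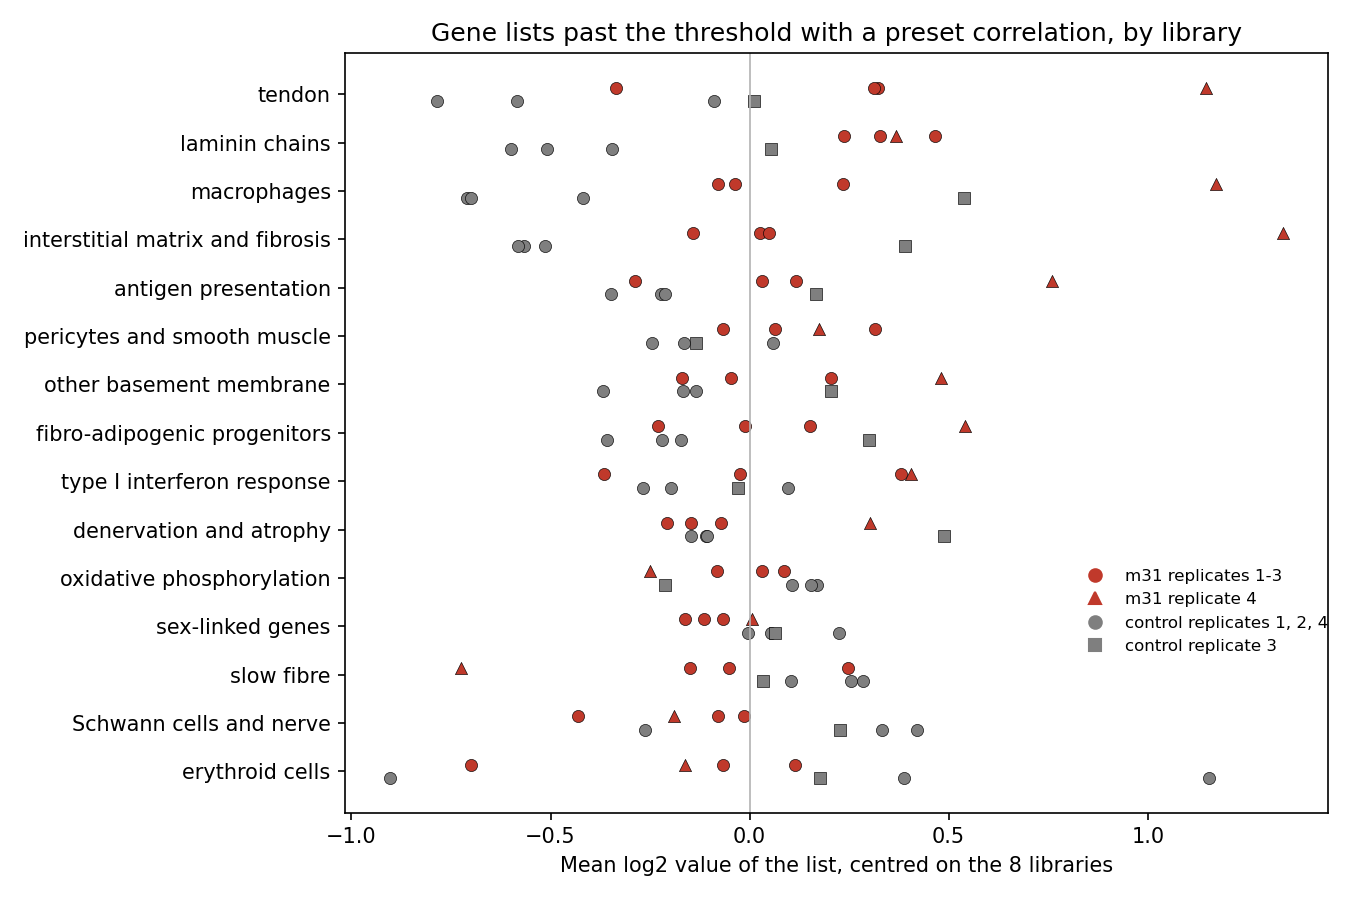
Mean log2 value of each of the 15 gene lists past the threshold with a preset correlation, centred on the 8 libraries (x axis), for each library, with m31 replicate 4 and control replicate 3 given their own symbols. In the matrix list m31 replicate 4 sits at 1.34 and control replicate 3 at 0.39, against -0.58 to 0.05 in the other 6 libraries.

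A further 4 lists were lower with m31, with no member past adjustment over the list alone. Oxidative phosphorylation had a mean log2 difference of -0.11 over 22 genes (camera adjusted p = 0.00064; adjusted p = 0.756 with an estimated correlation), with Ndufs1 at -0.23 and Cycs at -0.25. Its scores were lowest in m31 replicate 4 (-0.25) and control replicate 3 (-0.21), and without m31 replicate 4 its mean was -0.04 (adjusted p = 0.172). The denervation and atrophy list had a mean of -0.06 over 14 genes (camera adjusted p = 0.0238, and 0.577 with an estimated correlation). Its estimates were negative for 9 genes and positive for 5, Musk (0.24) among the 5. Its members Hdac4 and Foxo3 were lower in all 4 m31 libraries than in any control library, with log2 differences of -0.39 and -0.19, and the ubiquitin ligase gene Fbxo32 had -0.38. This list scored highest in control replicate 3 (0.49) and m31 replicate 4 (0.30), and it was lost without control replicate 3, m31 replicate 1 or m31 replicate 2 (adjusted p = 0.281, 0.104 and 0.0627). Its mean ranged from -0.198 without m31 replicate 4 (adjusted p = 0.00229) to -0.004 without m31 replicate 1. The 4 Y-linked genes, present in all libraries, had a mean of -0.17 (camera adjusted p = 0.017; adjusted p = 0.577 with an estimated correlation), and the 5 erythroid genes, the haemoglobins among them, -0.41 (camera adjusted p = 0.0391; adjusted p = 0.699 with an estimated correlation), with control scores from -0.90 to 1.15. The Y-linked list was lost without m31 replicate 2 (adjusted p = 0.0607) or control replicate 4 (0.0599), and the erythroid list without any of m31 replicates 1 and 4 and control replicates 1 to 3 (0.0623 to 0.600). The erythroid mean shrank to -0.09 without control replicate 2 and to -0.24 without m31 replicate 1.

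The other lists did not pass, so that 18 of 33 tested lists had camera adjusted p from 0.0663 to 0.992. Among them were fast fibre genes, with Mylpf at -0.29 (list adjusted p = 0.0757), fatty acid oxidation, with Acadm at -0.25 (0.0756), endothelium (0.230), heat shock, with Bag3 at 0.39 (0.508), satellite cells (0.523), glycolysis (0.809), and muscle regeneration, with Myod1 at 0.31 (0.992). Fast fibre genes passed as lower in 7 of 22 other settings, among them without control replicate 3 (mean -0.18, adjusted p = 9.8e-05); fatty acid oxidation passed in 4, heat shock in 3, and endothelium and the Lama1 neighbours in 2 each. In all, 9 of the 33 lists were higher and 6 lower with the preset correlation, 0 passed with an estimated correlation and 0 by fry, whose smallest adjusted p was 0.492; fry's mixed test, for change in either direction, called 1, the laminin chains (adjusted p = 0.00358), a list that holds Lama1 and was not tested in this way without it.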

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

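Except for the comparisons with tendon, lung and liver genes, the tests in this part were chosen after the result was seen; the settings without m31 replicate 4 and with an estimated correlation were planned, but their use for the third pattern was not. Values below are libraries far from the other 3 of their group by Dixon's criterion at the 95% level. Of 230 groups of 4 values examined for genes named by rule, gene lists, construct entries and library measures, 18 had such a library where chance gives about 1 in 20, or 11.5; 5 of the 18 lay in m31 replicate 4 and 7 in control replicate 3. A further 7 are of Mmp13, Cthrc1, Postn, Mymk, Myh3 and Sftpc, which were picked out after their values were seen.

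In m31 replicate 4, Mmp13, a collagenase gene, stood at 2338 normalised reads against at most 2.70 in the other m31 libraries, Cthrc1 at 365 against at most 13.5, Postn at 5250 against at most 522 and Mymk, the myoblast fusion gene, at 84.9 against at most 5.70. Dpp4 was high at 279, and the slow fibre genes Myh7 (2905) and Tnnc1 (776) were low. The matrix list scored 1.34 and the muscle regeneration list 0.63. In control replicate 3, Postn stood at 1014 against at most 293 in the other control libraries, Lox at 571, Lama4 at 1543, Lamb1 at 1826, embryonic myosin Myh3 at 681 and Sftpc at 95.5 against 0. Its list scores were high for matrix (0.39) and denervation and atrophy (0.49) and low for fast fibre (-0.26) and oxidative phosphorylation (-0.21).

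The first pattern is that m31 replicate 4 stands apart in matrix and macrophage genes, by 1.36 and 1.13 on the log2 scale from the mean of the other 3 m31 libraries. A wrong label is argued against by Lama1, at 86.5 against at most 4.18 in the control libraries. The endothelium list differed by -0.20, which argues against a lower share of fibre RNA in which every other cell type rises alike. A lower share in which only some cell types rise was not tested and stays open. Tendon tissue stays open: the 8 tenocyte genes, all also in the tendon list, differed by a median of 1.04, below the 1.23 of the matrix genes but not far below. Local tissue repair in this muscle stays open: the muscle regeneration list scored 0.63 against -0.22 to -0.12 in the other 3 m31 libraries, but that value was seen before the test was chosen. Control replicate 3 scored 0.52 on it, with a matrix score of 0.39 against 1.34. The design names no biological factor that sets this library apart, so beyond this list score no biological explanation was tested.

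The second pattern is the presence of Sftpc and Alb reads in control replicate 3, 85 and 124 reads. RNA of liver tissue in the library may account for Alb: of 8 other liver genes with values, 8 were highest in this library, from 6.74 (Apoc3) to 21.4 (Apoa1), and 6 were second highest in control replicate 1, which held 62.8 of Alb. Of the 9 liver genes measured, 1 reached a mean of 10 in the other 7 libraries. RNA of lung tissue cannot be told apart from another source, because 1 of the 3 transcripts chosen for the test was measured and the other 2 were not analysed here: Sftpb stood at 24.7% of Sftpc, at 23.6 against at most 4.0 elsewhere. The other 3 lung genes with values did not stand out in this library: Ager was 12.4 against at most 12.3 elsewhere, Napsa 16.9 against at most 23.2 and Lamp3 10.1 against at most 13.5. No biological explanation was tested, since the design gives none.

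The third pattern is that the list calls of matrix, tendon and macrophage genes could come from m31 replicate 4 alone. Without that library the lowest of the 3 mean log2 differences was 0.30, so the estimates kept their direction. All 3 lists remained past the threshold with the preset correlation of 0.01. The estimated correlations were 0.64 (matrix), 0.77 (tendon) and 0.82 (macrophages), so that test takes members that move together as nearly independent. Staying past it therefore cannot decide whether a difference beyond the spread remains without m31 replicate 4. The matrix and macrophage means fell from 0.64 and 0.64 to 0.30 and 0.36, so a part came from it. With all 8 libraries and an estimated correlation the 3 lists did not pass (adjusted p = 0.577 each), so their calls rest on the preset correlation.

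Other libraries far from their group were B3galnt2 in m31 replicate 3 (2616, low), Dmd (2056, high), Fmod (5694, low) and the circadian clock list (-0.11, low) in m31 replicate 1, and H2-D1 (2980, low) and the endothelium list (-0.15, low) in control replicate 4.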

How the results depend on the processing

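The settings with edgeR, with the GNDM level as a covariate and without both m31 replicate 4 and control replicate 3 were chosen after seeing the data. Lama1 was past the threshold in every setting run, with log2 differences from 4.98 (pseudocount 5) to 7.22 (without m31 replicate 4 and control replicate 3), and 6.26 to 7.05 with 1 library left out. The count of genes was 1 to 2 with 1 library left out: without m31 replicate 1 it was 2 (Gm10524, lower) and without control replicate 4 also 2 (Xlr3b, lower), both named after their values were seen. It was 3 without m31 replicate 4 and control replicate 3 (Pde10a and Cilp, higher, named likewise) and 31 with DESeq2 on recovered reads, of which 29 had non-overlapping groups; the cause was not tested. All other settings run gave 1. The count of lists was 11 to 16 with 1 library left out, lowest without m31 replicate 4, and 13 to 17 in the other settings, except for 0 with the correlation estimated per list, whose construction widens the error where members move together. With Lama1 left out of the lists it was 14, and with edgeR 16. The labels do not say that equal replicate numbers pair the samples. Deviations of same-numbered libraries correlated at 0.05, -0.05, -0.13 and -0.18, and no m31 library correlated best with the control library of its number. So few pairs cannot exclude a shared litter, day or batch. With the replicate block, 1 gene passed, Lama1 at 6.60 (adjusted p = 0.0120), and 16 lists. Of 2918 further values of genes named by the fixed rule, 0 crossed the threshold, with 52 changes of sign among genes not past it in either setting. Genes picked out after their values were seen are not among these, and Neto2, Pthlh, Ephx3, Glcci1 and Xlr3a passed with DESeq2. Of 721 further list values, 48 lost and 20 gained the threshold, and 54 not past it changed sign. Depth (25157486 to 39210248 reads) limits only low genes such as Lama1 under the control guide, with 7 reads in all.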

Other observations

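The comparison of Lama1 with GNDM was chosen after the result was seen; the tests on interferon genes and on other groupings of the libraries were set before theirs.

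Among members of the muscle regeneration and the denervation and atrophy lists, m31 replicate 4 and control replicate 3 shared high transcripts, picked out after their values were seen. Embryonic myosin Myh3 stood at 344 and 681 normalised reads in these libraries against 70.1 to 193 in the other 6, the fusion gene Mymk at 84.9 and 40.5 against at most 5.70, and Chrng, the fetal acetylcholine receptor subunit, at 40.9 and 36.0 against at most 9.10. A further 7 genes, not a fixed list, were likewise picked out, so their high values in m31 replicate 4 are no test of a cause. Of these 7, 2 were raised in both libraries. Postn was 5250 in m31 replicate 4 and 1014 in control replicate 3 against at most 522 in the other 6. Adam12 was 287 and 55.1 against at most 29.4. The other 5 stood out in m31 replicate 4 alone: Mmp13 was 2338 and 0, Cthrc1 365 and 15.7, Lrrc15 235 and 15.7, Acan 107 and 3.37 and Tnn 78.5 and 3.37. The immunoglobulin gene Ighg1 stood at 252 and 0. They also held the lowest (6157) and the highest (37989) GNDM level of the 8 libraries.

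Among genes that failed the adjustment, picked out after their values were seen, Ephx3, an epoxide hydrolase gene, had 62.2 ± 6.29 normalised reads with m31 and 26.4 ± 3.35 with the control guide, and Glcci1 29.1 ± 4.59 and 9.34 ± 0.73. Xlr3a, an X-linked gene, had 19.2 ± 9.05 and 66.5 ± 17.8. In each of these 3 genes all 4 m31 libraries lay on one side of all 4 control libraries (limma adjusted p = 0.216, 0.216 and 0.273), and all 3 passed with DESeq2 on recovered reads (adjusted p = 0.0013, 0.0135 and 0.000394).

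A hypothesis is that Lama1 follows the GNDM level in the 4 m31 libraries. The coefficient of variation was 43.4% for Lama1, 52.2% for GNDM and 17.2% for Lama1 divided by GNDM, and of the 24 ways to pair the 4 values, 1 gave a ratio this even (exact one-sided permutation p = 0.0417, the smallest that 4 libraries allow). This rested on m31 replicate 4: without it the coefficient of variation was 17.2% for Lama1 and 19.7% for the ratio. A dependence on construct level therefore cannot be told apart from the low value of 1 library, with 4 libraries in all.

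A second hypothesis was that interferon and antigen presentation genes rise with the GNDM level. With guide in the model, the mean slopes per doubling of GNDM were -0.12 and -0.05, the opposite of a rise. Their camera adjusted p was 0.00193 and 0.353 at the preset correlation. With an estimated correlation the smaller adjusted p was 0.791. Calling neither list in that test was the outcome set beforehand to count against a rise. That test called 0 of the 33 lists, however, so its outcome weighs little. No rise was seen, and a rise too small for these libraries stays open. The slope test called 2 of 15960 genes, with 997 at an unadjusted p under 0.05.

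Chance could not be excluded as the source of the counts. There are 35 ways to split the 8 libraries into groups of 4, and each count below includes the real split itself. At least as many genes as in the real split (1 gene, highest other 4) came from 2, while 33 gave no gene. At least as many lists (15, highest other 19) came from 8. With DESeq2 on recovered reads, at least as many genes (31, highest other 315) came from 6. The highest for genes, with both tools, was m31 replicate 1 with control replicates 1, 2 and 4 against the rest, several times the real count. Such a split points to a structure of the samples, whose source was not tested, and it was picked as the largest of the 34 others. These counts do not bear on the size of the Lama1 difference, which separated the guides in all 8 libraries.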
